A study of Mus musculus with 12 samples.

How the data were processed

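The deposited table held log2 values that, per the labels, the authors had made with the RMA method, which corrects background, normalises arrays by quantiles and summarises probes to 1 value per probe set. The version of RMA and the probe-set definition behind it are not given in the sources used here. The scanner files were not used here, so background correction and normalisation were not redone. The labels also state that total RNA was isolated with on-column DNase treatment and amplified as cDNA with a kit for small inputs before labelling. Each of the 12 columns was assigned to a source from its label, 3 arrays for each of 4 groups, and 0 columns were left unassigned. The values fitted the stated log2 unit when tested on the table.

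The table held 21625 probe sets, of which 64 were Affymetrix controls and 21561 carried a RefSeq accession. Symbols came from the RefSeq table of the mouse assembly GRCm38.p6 alone. It gave 1 symbol for 16537 of them, several for 0 and none for 5024, of which 4647 were predicted and 377 curated transcripts. For the 987 genes with over 1 probe set, the probe set with the highest mean over the 12 arrays was used, which left 15204 genes. No gene was filtered for low values. The no-target level of an array was the 95th percentile of 27 bacterial control probe sets, between 4.01 and 4.46. For a gene at or under it on every array of a group, the fold difference is a bound from that level, and where both groups lay there no fold is given.

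Differences were estimated with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings) in 1 model of 4 group means over all 12 arrays, with 8 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and a gene was called at an adjusted p under 0.05 and an absolute log2 difference of at least 1, a 2-fold difference. A gene said not to pass may thus differ clearly by less than 2-fold. SE is the moderated standard error from limma and SD the spread of the 3 arrays. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. The groups, 5 comparisons, 27 gene lists, thresholds and alternatives were chosen before the data were examined. The main model did not use the replicate numbers in the labels. After the group means were removed, the 3 pairs of single-cultured and co-cultured arrays with the same number correlated at 0.227, 0.135 and 0.232. All lay above 0.1, and in no other pair of groups did all 3. Pairing of the single-cultured and co-cultured arrays is therefore possible but not shown, and the labels do not state it. Some arrays with different numbers correlated as highly, such as non-cultured replicate 1 and single-cultured replicate 3 (0.287).

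The 27 lists were written from general knowledge and covered amino acid transporters, barrier transporters and receptors, ABC transporters, tight junctions, endothelial identity, Wnt and barrier factors, leukocyte adhesion and chemokines, caveolae, mesenchymal and matrix genes, cell cycle, immediate early genes, ATF4 targets, glycolysis and hypoxia, oxidative phosphorylation, cholesterol, interferon response, tip cells, zonation, drug-metabolising enzymes, markers of pericytes, fibroblasts, astrocytes, microglia and macrophages, oligodendrocytes, neurons and blood cells, and housekeeping genes. Most of their genes were measured, such as 49 of 54 amino acid transporters and 36 of 36 barrier transporters, while Gfap of the astrocytes was not. Each list was tested against all other genes with camera from limma at its preset correlation of 0.01, and the p-values were adjusted over 135 tests. A second camera test estimated the correlation between members, and its adjusted p is given wherever it removed a call. Elsewhere mostly the preset value is printed, which can be far smaller than the estimated one and should not be read as that certain. Members were also tested with the adjustment over the list alone.

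Genes were named by a rule written beforehand. It took, for each comparison, the 5 called genes with the largest rise and the 5 with the largest fall among those whose 3 against 3 arrays did not overlap, up to 2 called members of each list with the largest rise and 2 with the largest fall, or the 1 member with the largest difference where none was called, and a fixed set of endothelial and amino acid transporter genes. This gave 495 values, of which 54 changed their call or moved by over 1.5 times when 1 array was left out. Genes named outside this rule, Axin2 and Apcdd1 in single-cultured cells and those in the closing section, were chosen after their values were seen.

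A self-test simulated 15204 genes on 12 arrays with the spread of the real data and 200 of them changed, 100 for each of 2 sizes. At a log2 change of 1.5 it recovered 95% of changed genes for single-cultured and 88% for co-cultured against non-cultured cells, 92% for b.End5 against non-cultured cells, 83% for co-cultured against single-cultured cells and 89% for b.End5 against single-cultured cells. At a change of 3 the shares were 98%, 99%, 99%, 97% and 99%. Between 1 and 3 unchanged genes were called and 0 changed genes had the wrong direction. A list shifted by 0.5 was called in all 5 comparisons, and 0 of 26 other lists were. The simulated genes varied independently of each other. The self-test therefore cannot show how often correlated members lead to false list calls.

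Alternatives replaced 1 choice at a time. They were centring each array on its median or on the housekeeping genes, cyclic loess, the mean or the most variable probe set of a gene or every probe set singly, leaving out the dimmest 30% of genes, trend and robust settings of eBayes, array weights, a model of the 2 groups compared only, an adjusted p under 0.01, no minimum difference, limma treat, camera with an estimated correlation, fry, replicates as a block, and each array left out in turn. Leaving out the array labelled b.End5 replicate 2 where that array is in neither group was added after seeing the data, as was a replicate block among the single-cultured and co-cultured arrays alone, with 6 residual degrees of freedom, and for the effect of co-culture on culture-induced shifts a correction by the covariance of these numbered arrays. For the overlap of comparisons and the effect of co-culture on culture-induced shifts, 100 simulated data sets of unchanged groups with the same shared arrays gave the values to compare with. Transcripts without a symbol were tested in the same way but are given only in the closing section. Results of 2 genes that met the naming rule are not reported here.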

Results

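Gene expression was measured on 12 microarrays of total RNA from mouse brain endothelial cells, 3 arrays for each of 4 sources. Non-cultured cells were brain microvascular endothelial cells purified with magnetic beads against PECAM1, an adhesion protein of the endothelial surface. Single-cultured cells were brain microvascular endothelial cells kept for 5 days on filters. Co-cultured cells were kept the same way above glial cultures 3 weeks old, without contact between the layers. The b.End5 cells are an endothelioma line, derived from transformed mouse brain endothelium. The labels name the PECAM1 step only for the non-cultured cells, so culture and bead sorting cannot be separated in any comparison with that group. They do not say whether replicates were separate cell preparations, so the p-values measure only the spread between these arrays, and the number of arrays limits the precision.

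Values for 15204 genes lay on the authors' log2 scale, with array medians between 7.21 and 7.40. Between 79.4% and 82.9% of the genes on each array lay above the level of control probe sets that have no target in mouse RNA. A gene at or under that level on all 3 arrays of a group is given a bound, as at least so many times higher or lower. Pearson's r across genes between arrays of a group, where genes are not independent replicates, was 0.994 in all 3 pairs of non-cultured arrays and 0.989 to 0.995 in single-cultured cells. It was 0.986 to 0.991 in co-cultured cells and 0.968 to 0.995 in b.End5. The group means of single-cultured and co-cultured cells correlated at 0.992, those of non-cultured and single-cultured cells at 0.944, and those of non-cultured cells and b.End5 at 0.898. The array labelled b.End5 replicate 2 stood apart from b.End5 replicates 1 and 3, with 1073 genes over 1 log2 unit from their mean, against 42 between those 2 arrays. Its sex-linked transcripts also differed from those of all other arrays, as given in the closing section. Counts without it, an alternative chosen after seeing the data, are given beside each comparison. To a lesser degree single-cultured replicate 2 lay away from its group, with 416 and 421 genes over 1 log2 unit from replicates 1 and 3. Those 2 arrays had 111 such genes between them, and pairs of co-cultured arrays had 316 to 645.

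**Figure D1:**
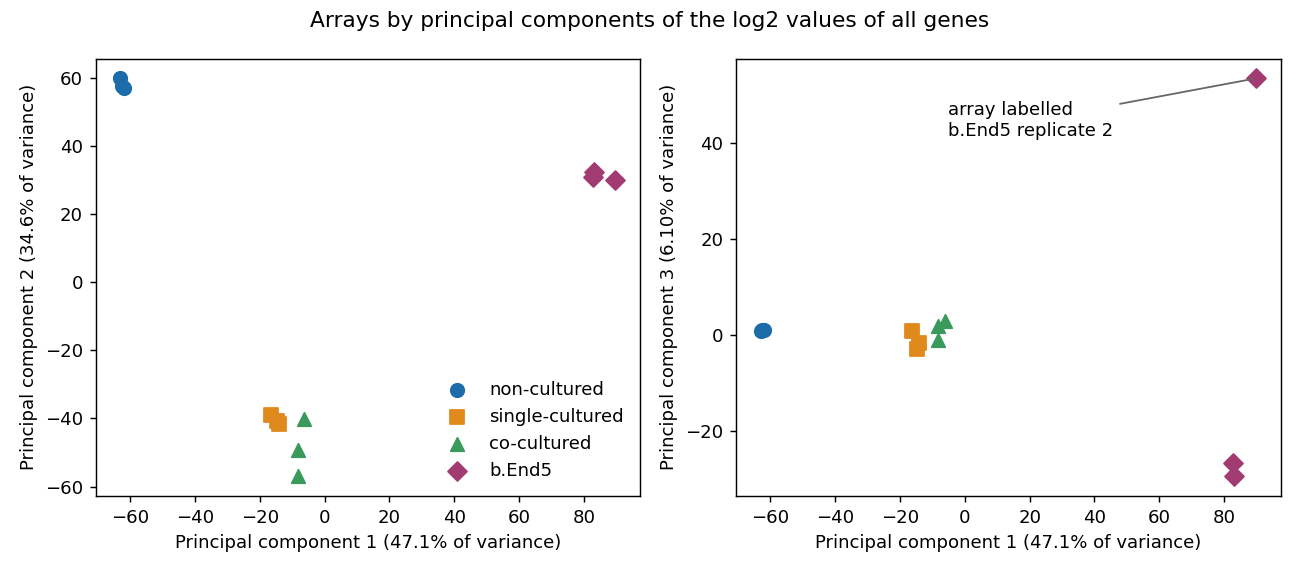
Scores of the 12 arrays (points, coloured by source) on principal components of the log2 values of all genes, in units of the centred log2 values. The left panel shows components 1 and 2 and the right panel components 1 and 3, with the percent of the variance on each axis (47.1%, 34.6% and 6.10%). The b.End5 arrays lie at 82.7 to 89.7 on component 1 and the non-cultured arrays at -62.9 to -62.0, while the single-cultured and co-cultured arrays lie together at -57.0 to -38.9 on component 2. On component 3 the array labelled b.End5 replicate 2 lies at 53.4 and b.End5 replicates 1 and 3 at -26.6 and -29.4.

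Single-cultured against non-cultured cells address what the title calls culture-induced change, with 3 arrays on each side. The large neutral amino acid transporter Slc7a5 was lower after culture, at 10.02 ± 0.26 (SD, n = 3) against 12.59 ± 0.16, a log2 difference of -2.56 (SE 0.45). Its heavy chain partner Slc3a2 fell by 1.83 (SE 0.13) and the cationic amino acid transporter Slc7a1 by 3.07 (SE 0.25). The glutamine transporters Slc38a3 and Slc38a5 fell most of the amino acid transporters, each with a difference of -4.22 (SE 0.22 and 0.19), Slc38a3 from 10.68 ± 0.11 to 6.46 ± 0.08. In the opposite direction, the cystine and glutamate exchanger Slc7a11 rose by 2.16 (SE 0.31), the glutamine transporter Slc38a1 by 1.79 (SE 0.16), the exchanger Slc7a6 by 1.33 (SE 0.29) and the neutral amino acid transporter Slc1a4 by 1.30 (SE 0.17). Of 49 measured amino acid transporters, 5 rose, 10 fell and 34 did not pass the test, with the same counts adjusted over the list alone. Slc1a2, a glutamate transporter of astrocytes, was among those that fell (-1.54), while the differences of Slc1a1 (-0.85), Slc38a2 (-0.51) and Slc1a5 (0.08) did not pass. The list as a whole did not pass camera, a test of a list against all other genes (adjusted p = 0.103), but did so with the dimmest 30% of genes left out (adjusted p = 0.0368).

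**Figure D2:**
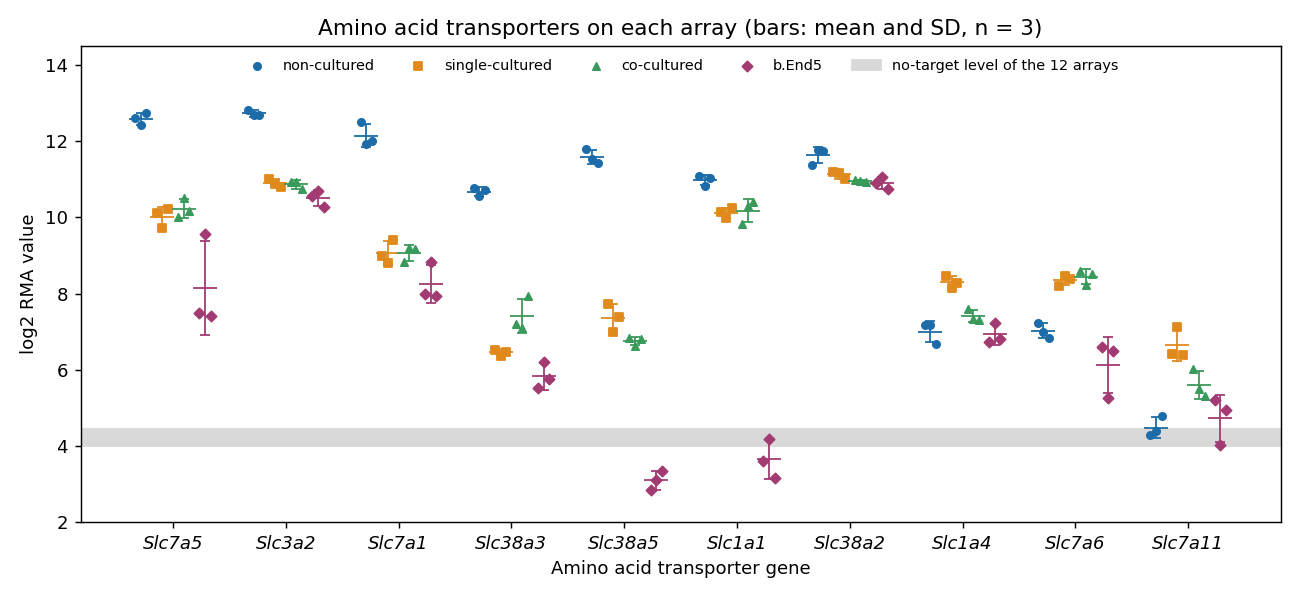
Log2 values of 10 amino acid transporter genes on each array (symbols by source), with bars for the mean and SD of 3 arrays and a grey band for the no-target levels of the 12 arrays (4.01 to 4.46). Slc38a5 and Slc1a1 lie at or under the no-target level in b.End5, and Slc7a5, Slc3a2, Slc7a1, Slc38a3 and Slc38a5 are lower on every array of the 3 cultured sources than on every non-cultured array.

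Blood-brain barrier transporters and receptors fell as a list in single-cultured cells, with 25 of 36 lower, 5 higher and 6 not passing (median log2 difference -1.60, adjusted p = 3.69e-12). The organic anion transporter Slc22a8 fell by 6.20 (SE 0.16), the lipid transporter Mfsd2a by 6.08 (SE 0.27) and the transferrin receptor Tfrc by 2.54 (SE 0.16). The iron carrier transferrin, Trf (2.69), and the ion cotransporter Slc12a2 (1.61) were higher, and the glucose transporter Slc2a1 did not pass (-0.31). Among Wnt signalling and barrier transcription factors 15 of 32 fell and 1 rose (median -0.94, adjusted p = 2.76e-11). Its largest falls were Klf2 (-5.35, SE 0.39) and Klf4 (-5.01, SE 0.25), known as flow-responsive factors. The Wnt targets Axin2 (-4.92, SE 0.23) and Apcdd1 (-4.12, SE 0.30) fell too, while the list's only rise was the Wnt target Sp5, from 7.85 ± 0.29 to 9.35 ± 0.36. Immediate early genes fell in 21 of 27 cases (median -2.61, adjusted p = 3.46e-15), led by Fosb (-8.20, SE 0.30) and the heat-shock gene Hspa1b (-6.84), a near-identical copy of Hspa1a, and the growth factor-induced gene Myc rose by 1.74. Cell cycle genes rose in 32 of 46 cases and 1 fell (median 1.52, adjusted p = 3.77e-24), among them cyclin Ccnb2 (4.00, SE 0.29) and the spindle checkpoint kinase Bub1, at least 10.4-fold higher. These 4 lists were the only ones of 14 called in this comparison that also passed with an estimated correlation. Without the array labelled b.End5 replicate 2 there were 6, with the mesenchymal and interferon lists (adjusted p = 0.0329 and 0.0253 with an estimated correlation). Adjusted over the list alone, the counts were the same except for 16 falls in the Wnt list.

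Of 57 mesenchymal and extracellular matrix genes 33 rose and 2 fell in the same cultures (34 and 2 adjusted over the list alone; median 1.44, adjusted p = 3.95e-14), with adjusted p = 0.0539 with an estimated correlation, or 0.0329 without the array labelled b.End5 replicate 2. The matrix protein Tnc, outside that list, had the largest rise of all genes that met the naming rule (8.38, SE 0.18, from 4.44 ± 0.12 to 12.82 ± 0.17), followed by the matrix protein Thbs1 (6.54), the collagen Col15a1 (6.32), the calcium-binding protein S100a6 (6.29) and the activin subunit Inhba (6.13). Angiogenic tip cell genes rose in 13 of 24 cases and fell in 2 (14 and 2 adjusted over the list alone; adjusted p = 8.66e-05, and adjusted p = 0.131 with an estimated correlation), with Angpt2 at 4.12 (SE 0.16) and Pgf at 4.08 (SE 0.20). Microglia and macrophage markers were higher beside these groups, 14 of 25 rising and 1 falling (16 and 1 adjusted over the list alone; median 1.55, adjusted p = 4.77e-05, and adjusted p = 0.374 with an estimated correlation). Lysozyme, Lyz2, rose from 9.74 ± 0.09 to 13.23 ± 0.39 and the microglial protein Aif1 by 3.90 (SE 0.49), while the macrophage receptor Cd163 was at least 5.25-fold lower. Pericyte and smooth muscle markers were called lower, with 4 higher and 9 lower of 22 (4 and 10 adjusted over the list alone; adjusted p = 0.0398, and adjusted p = 0.512 with an estimated correlation). The pericyte genes Rgs5 (-5.79) and Vtn (-3.95) fell, while Acta2 (2.94) and Tagln (3.66), contractile proteins that stressed or transformed cells of several kinds also make, rose. The pericyte call ended without non-cultured replicate 3 (adjusted p = 0.111) or single-cultured replicate 1 (adjusted p = 0.0700), and with each of 3 other scalings (adjusted p = 0.0514 to 0.105) or the filter on dim genes (adjusted p = 0.118).

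Metabolic and response lists moved too, none of them passing with an estimated correlation on all arrays. Amino acid response and ATF4 targets rose in 12 of 35 cases and fell in 3 (13 and 3 adjusted over the list alone; adjusted p = 1.93e-04, and adjusted p = 0.320 with an estimated correlation), led by the folate enzyme Mthfd2 (4.11) and the lipoprotein receptor Vldlr (3.14). Glycolysis and hypoxia genes rose in 7 of 24 cases (adjusted p = 0.00343, and adjusted p = 0.216 with an estimated correlation). The oxygen sensor Egln3 was among them (5.43), from a non-cultured mean of 4.10 near the no-target level. Cholesterol genes rose in 5 of 24 cases (adjusted p = 0.00136, and adjusted p = 0.223 with an estimated correlation), including Sqle (2.10) and Msmo1 (2.05). Interferon response genes fell in 17 of 31 cases and 1 rose (median -1.18, adjusted p = 1.68e-07, and adjusted p = 0.374 with an estimated correlation, or 0.0253 without the array labelled b.End5 replicate 2). Irf7 (-3.83) and Rsad2 (-2.87) fell, and Irf8, a factor of myeloid cells, rose by 2.44. The mean of Irf8 was 5.16 in non-cultured and 7.59 in single-cultured cells. It lay at 7.68, 5.64 and 7.51 on the b.End5 arrays, so that gene does not mark myeloid cells alone. Astrocyte markers fell in 8 of 23 cases, or 4 without non-cultured replicate 3, and 1 rose (adjusted p = 0.0339, and adjusted p = 0.153 with an estimated correlation), with Slco1c1, also expressed by the non-cultured endothelial samples (13.80), among those that fell. That call ended without single-cultured replicate 2 (adjusted p = 0.0549) or b.End5 replicate 2 (adjusted p = 0.0518) and with centring on the median (adjusted p = 0.0646) or the housekeeping genes (adjusted p = 0.0592). Erythrocyte and lymphocyte markers fell in 5 of 10 cases (adjusted p = 6.42e-05, and adjusted p = 0.0860 with an estimated correlation), Alas2 by 3.79. Adjusted over the list alone, these last 5 lists kept their numbers of rises and falls.

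The junction and adhesion genes Pecam1, Cdh5 and Cldn5 had group means of 11.78 or more in every source. Pecam1 (0.34), the junction cadherin Cdh5 (0.48) and the claudin Cldn5 (-0.78) did not pass between single-cultured and non-cultured cells, nor did Tjp1 (-0.42), Ocln (-0.79), Icam1 (-0.06), Vcam1 (0.77) or Abcg2 (-0.76). All these differences lay under the 2-fold minimum, so none could be called whatever its p-value. Of these genes only Pecam1 and Icam1 had overlapping arrays, while 45.3% of all genes had arrays that did not overlap. The fenestral diaphragm protein Plvap rose by 2.09 (SE 0.52). Among the lists that did not pass camera, endothelial identity genes rose in 2 and fell in 6 of 35 cases (adjusted p = 0.288) and tight junction genes rose in 2 (0 without non-cultured or single-cultured replicate 2) and fell in 4 of 28 (adjusted p = 0.206), Lsr by 3.89 and Jam2 by 3.53. In the ABC transporters 6 rose and 3 fell of 28 (adjusted p = 0.874; median -0.10, mean 0.17, so the signs differ). Abcb1b rose by 3.57 while its close relative Abcb1a, the main P-glycoprotein gene of brain endothelium, fell by 2.25. Leukocyte adhesion genes and chemokines rose in 10 and fell in 4 of 32 cases (adjusted p = 0.136), with Ccl2 at 5.10 and Ackr1 at 4.86. Caveolae and transcytosis genes rose in 6 and fell in 2 of 20 (adjusted p = 0.118). Drug-metabolising enzymes rose in 8 and fell in 10 of 33 (adjusted p = 0.105), and fibroblast markers rose in 3 (1 without non-cultured replicate 1) and fell in 1 of 18 (adjusted p = 0.966). Neuron markers rose in 1 and fell in 2 of 27 (adjusted p = 0.0968). Oligodendrocyte markers rose in 3 of 21 (adjusted p = 0.990; median -0.09, mean 0.10). No gene of 46 in oxidative phosphorylation or of 14 in the housekeeping list was called by limma, with 9 and 4 at an unadjusted p under 0.05 (adjusted p = 0.110 and 0.382), and the first list passed without single-cultured replicate 2 (adjusted p = 0.0341). Its member Ndufa7 (-1.04), a subunit of complex I, was called lower with cyclic loess (adjusted p = 0.0368), with centring on the median (0.0426) or the housekeeping genes (0.0160), with the dimmest genes left out (0.0427), and without single-cultured replicate 3 (-1.40) or b.End5 replicate 2 (-1.04). Much of that fall came from single-cultured replicate 2. Ndufa7 lay at 9.78, 8.44 (replicate 2) and 10.2 on the single-cultured arrays, against 10.6, 10.4 and 10.5 on the non-cultured ones. Zonation genes rose in 4 and fell in 10 of 30 (4 and 11 adjusted over the list alone, the other lists of this paragraph unchanged; adjusted p = 0.0552). That list passed with cyclic loess (adjusted p = 0.0360) and without non-cultured replicate 1 or 2 or single-cultured replicate 1, 2 or 3 (adjusted p = 0.0366, 0.0481, 0.0450, 0.0485 and 0.0495), and had adjusted p = 0.246 with an estimated correlation.

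In all, 1976 of 15204 genes were called between single-cultured and non-cultured cells, at a limma adjusted p under 0.05 and at least a 2-fold difference, 1091 higher and 885 lower. The split was 978 and 978 with median centring, and 957 higher and 1013 lower with centring on the housekeeping genes. With the scale as deposited, 444 rose and 296 fell over 4-fold. The largest falls that met the naming rule were Fosb, the aromatic amino acid decarboxylase Ddc (at least 83.4-fold), the carbonic anhydrase Car4 (-7.33), the phosphatase Ptprr (-7.16) and Hspa1b. The 3 against 3 arrays did not overlap in 45.3% of all genes, where chance gives 10%. Without the array labelled b.End5 replicate 2, which enters through the shared spread, 2066 genes were called, and all 1976 were among them.

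**Figure D3:**
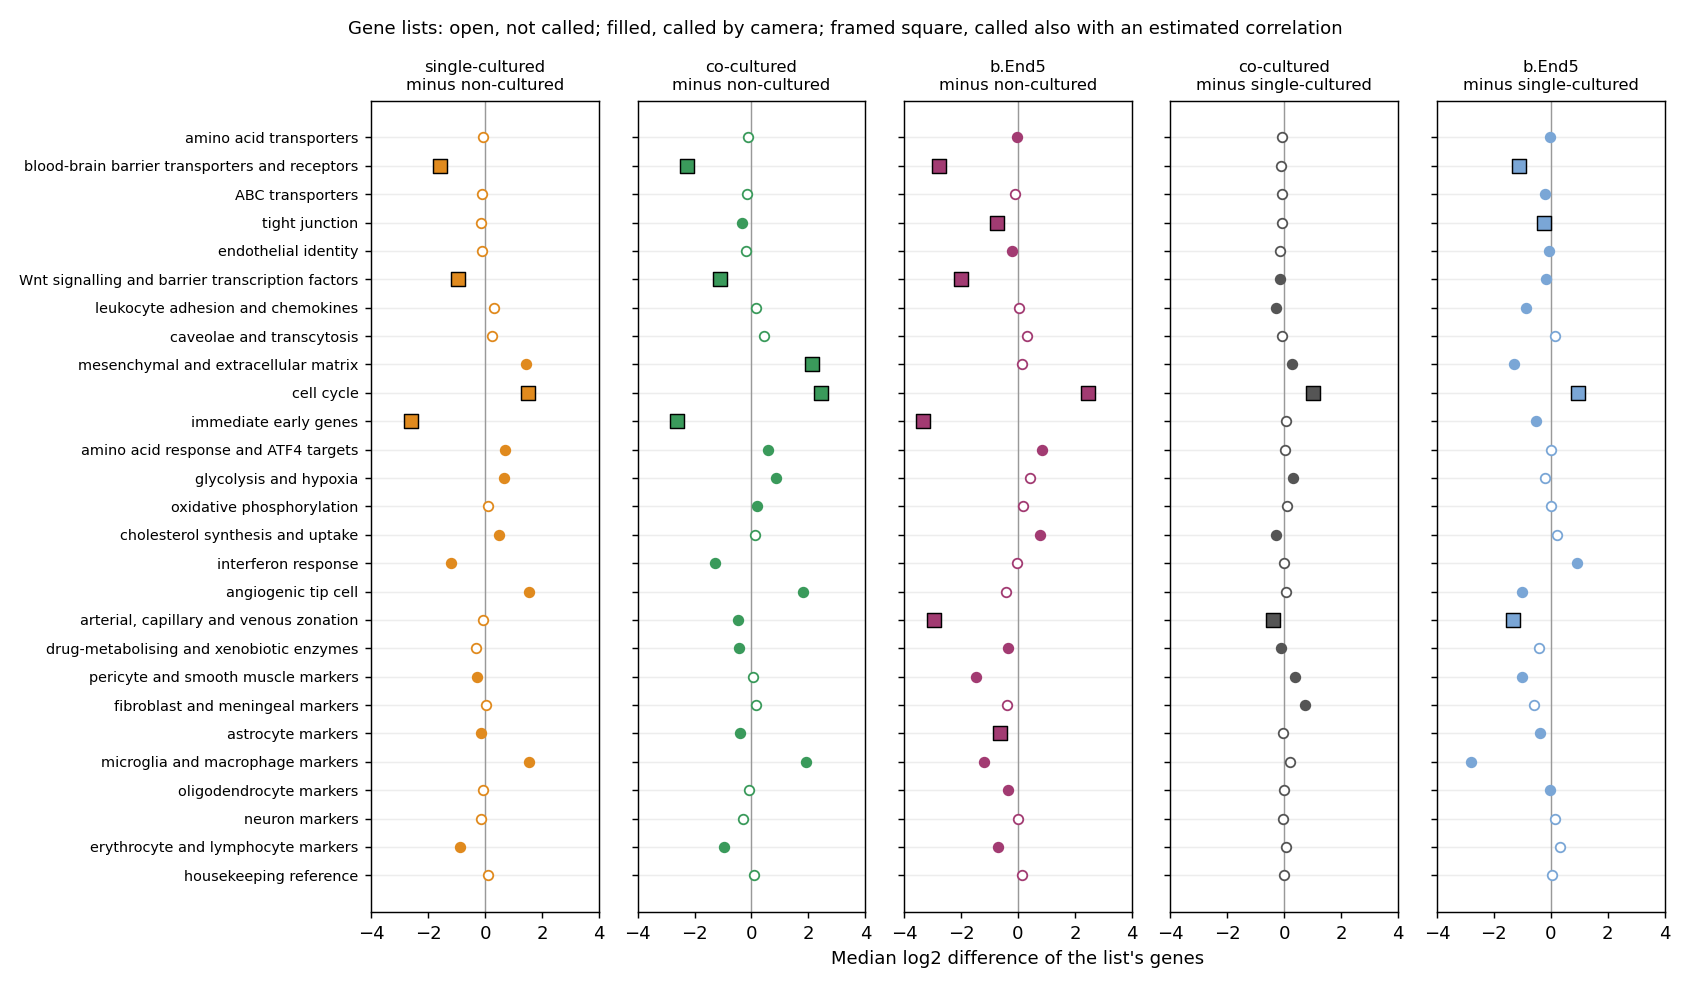
Median log2 difference of the measured genes of each of 27 lists (vertical axis) in the 5 comparisons (panels), with open circles for lists not called by camera, filled ones for called lists and framed squares for those called also with an estimated correlation. Barrier transporters, Wnt and barrier factors and immediate early genes lie below 0 and cell cycle genes above 0 in the 3 comparisons with non-cultured cells, all framed.

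Co-cultured against non-cultured cells put the same question with glial cultures in the well. Slc38a5 fell by 4.83 (SE 0.19), the cationic amino acid transporter Slc7a3 by 3.87 (SE 0.43), Slc38a3 by 3.27 (SE 0.22), Slc7a1 by 3.08 (SE 0.25), Slc7a5 by 2.36 (SE 0.45) and Slc3a2 by 1.86 (SE 0.13), with n = 3 arrays in each group. Slc7a6 rose by 1.42 (SE 0.29), the glutamate transporter Slc1a6 by 2.14 (SE 0.37) and the neutral amino acid transporter Slc38a4 at least 3.18-fold. Of 49 amino acid transporters 6 rose and 11 fell, with the same counts adjusted over the list alone. The list did not pass camera (adjusted p = 0.0558) but did so without non-cultured replicate 1 (adjusted p = 0.0352), without co-cultured replicate 1 (adjusted p = 0.0364) or with the dimmest 30% of genes left out (adjusted p = 0.00731). Barrier transporters fell in 24 of 36 cases and rose in 3 (median -2.27, adjusted p = 1.25e-11), with Slc22a8 at -6.38 (SE 0.16) and the thiamine transporter Slc19a3 at -5.84 (SE 0.22), against the endocytic receptor Lrp1 at 1.82. Wnt and barrier factors fell in 16 of 32 cases and rose in 1 (1 and 17 adjusted over the list alone; median -1.09, adjusted p = 1.99e-11), with the Wnt target Axin2 at -5.56 (SE 0.23) and Klf4 at -5.06. Its only rise was again Sp5 (1.14, SE 0.23), not called without non-cultured replicate 1 (0.98) or with centring on the median (0.99) or the housekeeping genes.

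Cell cycle genes rose in 42 of 46 cases in co-cultured cells (42 higher and 1 lower adjusted over the list alone; median 2.44, adjusted p = 1.71e-32), with the mitotic regulators Birc5 at 5.19 (SE 0.13) and Bub1 at least 30.1-fold higher. Immediate early genes fell in 19 of 27 cases and rose in 1 (median -2.63, adjusted p = 2.8e-12). Mesenchymal and matrix genes rose in 36 of 57 and fell in 2 (median 2.13, adjusted p = 1.1e-15), and this list too passed with an estimated correlation (adjusted p = 0.0417). The fibrillar collagens Col1a1 (4.17, SE 0.51) and Col3a1 (4.10, SE 0.46) rose, while the laminin chain Lamb2 fell by 2.35. Microglia and macrophage markers rose in 17 of 25 cases beside them, or 11 without non-cultured replicate 1 or co-cultured replicate 1, and 1 fell (18 and 1 adjusted over the list alone; median 1.91, adjusted p = 4.24e-06, and adjusted p = 0.326 with an estimated correlation), the complement gene C1qb by 3.84 (SE 0.59). The macrophage elastase Mmp12 was at least 48.7-fold higher. Tip cell genes rose in 15 of 24 and fell in 2 (adjusted p = 5.3e-05, and adjusted p = 0.124 with an estimated correlation). Glycolysis and hypoxia genes rose in 10 of 24 and fell in 2 (adjusted p = 1.85e-04, and adjusted p = 0.135 with an estimated correlation). ATF4 targets rose in 13 of 35 and fell in 3 (14 and 3 adjusted over the list alone; adjusted p = 5.12e-04, and adjusted p = 0.355 with an estimated correlation). Interferon genes fell in 18 of 31 and rose in 1 (1 and 20 adjusted over the list alone; median -1.28, adjusted p = 2.51e-06, and adjusted p = 0.417 with an estimated correlation, or 0.0269 without the array labelled b.End5 replicate 2), Isg15 by 2.78. Zonation genes fell in 9 of 30 and rose in 1 (adjusted p = 4.6e-04, and adjusted p = 0.0749 with an estimated correlation), among them the capillary gene Spock2 (-6.96) and the arterial gene Gkn3 (-5.54). Erythrocyte and lymphocyte markers fell in 5 of 10 (adjusted p = 0.001, and adjusted p = 0.135 with an estimated correlation). Adjusted over the list alone, the remaining lists named here kept their counts.

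Tight junction genes (2 higher, or 0 without co-cultured replicate 3, and 5 lower of 28, adjusted p = 0.0456), drug-metabolising enzymes (6 and 12 of 33, adjusted p = 0.0317), astrocyte markers (2 and 7 of 23, adjusted p = 0.0352) and oxidative phosphorylation (adjusted p = 0.0134) were called by narrow margins in co-cultured cells, with the same counts adjusted over the list alone. They had adjusted p = 0.132, 0.125, 0.153 and 0.443 with an estimated correlation. Of the 46 oxidative phosphorylation genes limma called 0, with 15 at an unadjusted p under 0.05. The tight junction call ended without non-cultured replicate 1 (adjusted p = 0.0511), the astrocyte call without co-cultured replicate 3 (adjusted p = 0.0741), and both without b.End5 replicate 2 (adjusted p = 0.0518 each). With each array centred on its median, the adjusted p of these 4 lists was 0.0577, 0.104, 0.0937 and 0.0541. Oxidative phosphorylation was further from passing with cyclic loess (adjusted p = 0.405) and with centring on the housekeeping genes (adjusted p = 0.0689). That centring also ended the calls of drug-metabolising enzymes (adjusted p = 0.102) and astrocyte markers (adjusted p = 0.0655). Leaving out the dimmest genes ended those of tight junctions (adjusted p = 0.0664) and oxidative phosphorylation (adjusted p = 0.0564). Cldn5 (-0.85) did not pass but was called lower with cyclic loess (-1.02) and, just past the 2-fold minimum, with median centring, and Ocln (-1.31) was called only with median centring (-1.46) or without b.End5 replicate 2. Pecam1 (-0.03) and Cdh5 (0.20) did not pass, and the efflux transporter Abcg2 fell by 1.46 (SE 0.11). Endothelial identity genes rose in 2 and fell in 5 of 35, also adjusted over the list alone (adjusted p = 0.0628, and adjusted p = 0.526 with an estimated correlation). That list was called lower with cyclic loess (adjusted p = 0.00275), with the dimmest genes left out (adjusted p = 0.0420) and without co-cultured replicate 3 (adjusted p = 0.0315).

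Of all genes, 2326 were called in co-cultured against non-cultured cells, 1384 higher and 942 lower. The largest rises that met the naming rule were Tnc (8.50), AA467197 (6.75), S100a6 (6.61), Mmp12 and Thbs1 (6.41), and the largest falls were Fosb (-8.25), Ddc (at least 96.7-fold), the sphingosine phosphatase Sgpp2 (-7.13), Spock2 and Ptprr (-6.88). The arrays did not overlap in 51.1% of genes, where chance gives 10%. Rises made up 59.5% of the calls, 49.0% with median centring and 49.4% with centring on the housekeeping genes, which moved the median of all genes from -0.04 to -0.19 and -0.18. The count was 2397 without the array labelled b.End5 replicate 2, with all 2326 among them.

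The b.End5 line against non-cultured cells asks how far a cell line carries the transcripts of the tissue cells. Slc38a5 was at least 159-fold lower in b.End5 and the glutamate transporter Slc1a1 at least 104-fold lower (n = 3 arrays in each group). Slc38a3 fell by 4.85 (SE 0.22), Slc7a5 by 4.43 (SE 0.45), Slc7a1 by 3.89 (SE 0.25) and Slc3a2 by 2.22 (SE 0.13). The cationic and neutral amino acid exchanger Slc7a7 rose by 2.53 (SE 0.21). On the b.End5 arrays Slc7a5 lay at 7.48, 9.57 (replicate 2) and 7.40. Replicate 2 thus makes the fall of Slc7a5 smaller, here and against single-cultured cells. It makes other falls of this comparison larger, among them those of Ocln, Vwf, Abcb1a and Vcam1. These lay at 4.31, 5.51, 5.39 and 5.18 on replicate 2. On replicates 1 and 3 Ocln lay at 6.79 and 7.06, Vwf at 8.07 and 8.68, Abcb1a at 7.48 and 7.35 and Vcam1 at 7.39 and 7.58. Of 49 amino acid transporters 2 rose and 13 fell, with the same counts adjusted over the list alone (adjusted p = 0.00420, and adjusted p = 0.153 with an estimated correlation). Leaving out the array labelled b.End5 replicate 2, 3 rose and 13 fell, and the list passed with an estimated correlation (adjusted p = 0.0295). Barrier transporters fell in 26 of 36 cases and rose in 2 (median -2.77, adjusted p = 3.11e-18), with the organic anion transporters Slco1a4, at least 710-fold lower, and Slco1c1 (-9.55, SE 0.15). Tfrc fell by 4.00 and Slc2a1 by 2.03 (SE 0.18), and Abcb1a fell by 6.23 (SE 0.42).

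Tight junction genes fell in 11 of 28 cases and rose in 2 in b.End5 (median -0.73, adjusted p = 5.5e-05), occludin, Ocln, from 12.39 ± 0.21 to 6.05 ± 1.51, while Cldn5 (-0.40), Cdh5 (-0.27), Pecam1 (-0.21) and Tjp1 (-0.58) did not pass. Wnt and barrier factors fell in 20 of 32 cases and rose in 2 (median -2.01, adjusted p = 1.58e-13), the Wnt target Apcdd1 by 8.26 (SE 0.30). Zonation genes fell in 19 of 30 and rose in 5 (median -2.95, adjusted p = 3.72e-08), with the arterial matrix protein Mgp at least 170-fold lower and the venous factor Nr2f2 higher (1.94). Cell cycle genes rose in 44 of 46 (44 higher and 1 lower adjusted over the list alone; median 2.48, adjusted p = 3.37e-27), and immediate early genes fell in 22 of 27 and rose in 1 (median -3.33, adjusted p = 2.29e-16). Astrocyte markers fell in 11 of 23 and rose in 1 (median -0.61, adjusted p = 5.11e-05). These 6 lists and the barrier transporters passed with an estimated correlation and kept their calls without the array labelled b.End5 replicate 2, with medians of -0.72, -1.93, -2.94, 2.47, -3.20, -0.79 and -2.81. Adjusted over the list alone, the counts not given were the same.

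Microglia and macrophage markers fell in 12 of 25 cases between non-cultured cells and b.End5 and rose in 2 (2 and 13 adjusted over the list alone; median -1.19, adjusted p = 5.63e-04, and adjusted p = 0.458 with an estimated correlation), the lysosomal protease Ctss at least 31.2-fold. Pericyte markers fell in 13 of 22 (median -1.46, adjusted p = 8.1e-08, and adjusted p = 0.135 with an estimated correlation), Rgs5 at least 110-fold. Oligodendrocyte markers fell in 7 of 21 and rose in 1 (adjusted p = 0.00147, and adjusted p = 0.114 with an estimated correlation). Fibroblast markers fell in 5 of 18, or 3 without non-cultured replicate 2 or b.End5 replicate 3, without passing as a list (adjusted p = 0.0550), except without non-cultured replicate 1 (adjusted p = 0.0245). Neuron markers rose in 4 and fell in 3 of 27 (median 0.01, mean 0.23, while camera's direction was down, adjusted p = 0.505). Endothelial identity genes fell in 7 of 35 and rose in 1 (adjusted p = 0.00495, and adjusted p = 0.363 with an estimated correlation), Sox17 by 6.02 (SE 0.38) and von Willebrand factor, Vwf, by 5.27 (SE 0.59). Cholesterol genes rose in 8 of 24 (adjusted p = 7.13e-04, and adjusted p = 0.216 with an estimated correlation). The ATF4 targets rose in 12 of 35 and fell in 2 (adjusted p = 0.00244, and adjusted p = 0.409 with an estimated correlation), or in 8 and 2 without the array labelled b.End5 replicate 2. Adjusted over the list alone, 13 ATF4 targets rose and 2 fell, and the counts not given were the same. Mesenchymal and matrix genes were split, 14 higher and 15 lower of 57 with the same counts adjusted over the list alone (median 0.16, mean -0.10, adjusted p = 0.371), S100a6 rising by 5.92 and fibronectin, Fn1, falling by 4.70. Plvap rose by 5.36 (SE 0.52) and the adhesion molecule Vcam1 fell by 4.19 (SE 0.49).

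Of all genes, 2761 were called between b.End5 and non-cultured cells, 1384 higher and 1377 lower. Without the array labelled b.End5 replicate 2 the count was 2842, 1466 higher and 1376 lower, and 2532 genes were called both ways. The largest rises were the growth factor-binding protein Igfbp5 (9.19), the receptor kinase Ephb1 (at least 162-fold), Serpina1b (at least 101-fold), the homeobox gene Meis2 (at least 103-fold) and the guidance protein Sema3a (7.52). Beside Slco1a4, Slco1c1 and Slc38a5, Fosb was at least 304-fold and the matrix-associated gene Itih5 at least 250-fold lower. The arrays did not overlap in 49.2% of genes, where chance gives 10%. Rises were 50.1% of the calls and 39.3% with centring on the housekeeping genes, which moved the median of all genes from 0.08 to -0.10.

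Co-cultured against single-cultured cells address the effect of glial co-culture, the only difference the labels name between these groups. A difference between cell preparations could not be told apart from that effect. Slc38a4 rose at least 2.93-fold (from under the no-target level to 5.84 ± 0.92, n = 3) and the taurine transporter Slc6a6 fell by 1.43 (SE 0.28), and these were the only 2 of 49 amino acid transporters called, against 2 higher and 1 lower adjusted over the list alone. The list did not pass camera (adjusted p = 0.238) but did so with the dimmest 30% of genes left out (adjusted p = 0.0378). The Slc6a6 call, and with it the count of 2, fell to 1 without single-cultured replicate 1 (difference -1.42) or 3 (-1.17) or co-cultured replicate 2 (-1.49) or 3 (-1.26), and without b.End5 replicate 2 Slc7a11 (-1.04) made the count 3. With the replicate number as a block among the cultured arrays, an alternative chosen after seeing the data, the count was 3, since the neutral amino acid transporter Slc1a5 was called higher (1.09, adjusted p = 0.0264). Slc38a3 was 0.95 higher (SE 0.22, adjusted p = 0.045), under the 2-fold minimum. Slc7a5 (0.20), Slc3a2 (-0.03), Slc7a1 (-0.01), Slc38a5 (-0.61) and Slc7a6 (0.09) did not pass. Cell cycle genes rose in 22 of 46 cases, or 14 without single-cultured replicate 1 or co-cultured replicate 1 (23 adjusted over the list alone; median 1.00, adjusted p = 5.02e-49), the cyclin Ccnb1 by 1.62 (SE 0.27) and Bub1 by 1.54 (SE 0.19). Zonation genes were called lower (median -0.40, adjusted p = 1.25e-05), with 2 of 30 falling (3 adjusted over the list alone). These were the arterial connexins Gja4 (-2.02, SE 0.26) and Gja5 (-2.28, SE 0.40), the second not called without single-cultured replicate 3 (-2.26). These were the 2 of 10 called lists that also passed with an estimated correlation. With the block among the cultured arrays, their camera adjusted p at the preset correlation was 1.85e-43 and 4.75e-06. With an estimated correlation it was only 0.0101 and 0.0326.

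Genes of matrix-forming and mural cells were higher with glia, without passing as lists with an estimated correlation. Fibroblast and meningeal markers rose in 3 of 18 cases, 5 without b.End5 replicate 2 and 1 without single-cultured replicate 1 or 3 or co-cultured replicate 2 (6 adjusted over the list alone or without co-cultured replicate 3; adjusted p = 2.93e-05, and adjusted p = 0.167 with an estimated correlation), Col1a2 by 2.86 (SE 0.48). Mesenchymal genes rose in 4 of 57, and in 1 without single-cultured replicate 1 or 3 or co-cultured replicate 2 (5 adjusted over the list alone; adjusted p = 3.45e-04, and adjusted p = 0.271 with an estimated correlation). Pericyte markers rose in 1 of 22, Rgs5 by 1.53, and in 2 without b.End5 replicate 2 (3 adjusted over the list alone; adjusted p = 1.04e-04, and adjusted p = 0.235 with an estimated correlation). Drug-metabolising enzymes fell in 5 of 33, the same number adjusted over the list alone and 2 without single-cultured replicate 3 (adjusted p = 0.00492, and adjusted p = 0.0569 with an estimated correlation), Cyp4b1 by 1.85 (SE 0.29). Leukocyte adhesion genes and chemokines fell in 2 of 32, the same number adjusted over the list alone and 5 without b.End5 replicate 2 (adjusted p = 0.00312, and adjusted p = 0.211 with an estimated correlation), the endothelial selectin Sele by 2.43 (SE 0.32). That call ended without co-cultured replicate 3 (adjusted p = 0.0919). Glycolysis and hypoxia genes were called higher with 1 of 24 rising (2 adjusted over the list alone or without b.End5 replicate 2; adjusted p = 5.76e-04, and adjusted p = 0.159 with an estimated correlation). Cholesterol genes and Wnt factors were called lower although limma called 0 of 24 and 0 of 32 members, also adjusted over the list alone, with 9 and 6 at an unadjusted p under 0.05 (adjusted p = 3.04e-04 and 0.0116). They had adjusted p = 0.185 and 0.220 with an estimated correlation, and the Wnt call ended without single-cultured replicate 3 (adjusted p = 0.0836) or co-cultured replicate 1 (adjusted p = 0.0501). Of 35 endothelial identity genes limma called 0, with 8 at an unadjusted p under 0.05, or 1 higher adjusted over the list alone (median -0.15, adjusted p = 0.0567, and adjusted p = 0.522 with an estimated correlation). That list was called lower with cyclic loess (adjusted p = 0.0231), and with the dimmest genes left out (adjusted p = 0.0378). The same held without single-cultured replicate 2 (adjusted p = 0.00138), co-cultured replicate 3 (adjusted p = 0.0109) or b.End5 replicate 2 (adjusted p = 0.0350). Of 25 microglia and macrophage markers limma called 0, with 2 at an unadjusted p under 0.05 (adjusted p = 0.0697). That list was called higher with centring on the median (adjusted p = 0.0231) or the housekeeping genes (0.0309), and without single-cultured replicate 1 (1.71e-04), co-cultured replicate 2 (0.0130) or co-cultured replicate 3 (4.75e-04), and with the block among the cultured arrays (0.0236). With an estimated correlation it did not pass (adjusted p = 0.669, and 0.503 with the block).

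Of all genes, 181 were called between the cultures, 137 higher and 44 lower with glia, and 11 rose and 10 fell over 4-fold. The largest rises were the receptor Tnfrsf9 (3.95, SE 0.27), the endothelin receptor Ednrb (3.54), the metalloproteinase Mmp9 (3.23), Col1a2 and the surface glycoprotein Thy1 (2.80). The largest falls were the monooxygenase Moxd1 (-3.44), the neutrophil protein S100a9 (-2.97), the cytochrome Cyp1a1 (-2.56), the nuclear protein Tox (-2.51) and Sele. Ednrb was not called without single-cultured replicate 1 (3.54) or 3 (3.42) or co-cultured replicate 2 (3.31), and Cyp1a1 not without single-cultured replicate 3 (-2.38). S100a9 was not called without single-cultured replicate 1 (-2.30) or 3 (-2.63) or co-cultured replicate 1 (-2.77), 2 (-3.02) or 3 (-3.12), nor with the replicate number as a block over all arrays (adjusted p = 0.0719), but it was called with the block among the cultured arrays. The count was 118 without single-cultured replicate 1 and 231 without the array labelled b.End5 replicate 2, and all 181 were among the 231. With the block among the cultured arrays it was 202, and 170 of the 181 were among them. Arrays did not overlap in 19.9% of genes, where chance gives 10%. Rises were 75.7% of the calls and 64.1% with median centring.

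The b.End5 line against single-cultured cells compares the line with primary cells that were also cultured. Slc1a1 was at least 57.4-fold and Slc38a5 at least 8.51-fold lower in b.End5, Slc7a6 fell by 2.22 (SE 0.29), Slc7a11 by 1.92 (SE 0.31), Slc7a5 by 1.87 (SE 0.45) and Slc1a4 by 1.38 (SE 0.17), and Slc7a7 rose by 1.65 (SE 0.21), with n = 3 arrays in each group. Of 49 amino acid transporters 2 rose and 11 fell, with the same counts adjusted over the list alone (adjusted p = 0.0189, and adjusted p = 0.216 with an estimated correlation). When the array labelled b.End5 replicate 2 was left out, 1 rose and 12 fell and the list passed with an estimated correlation (adjusted p = 0.0338), and without b.End5 replicate 1 the list did not pass (adjusted p = 0.0509). Barrier transporters fell in 19 of 36 cases and rose in 4 (median -1.13, adjusted p = 2.16e-10), Slco1a4 at least 215-fold, while the insulin receptor Insr rose by 2.41. Cell cycle genes rose in 22 of 46 (median 0.97, adjusted p = 4.03e-15), among them the inhibitor Cdkn2c (1.88), which slows the cycle, and the thymidine kinase Tk1 (1.70). Tight junction genes fell in 9 of 28 and rose in 3 (median -0.23, adjusted p = 6.13e-04), Ocln by 5.54 (SE 0.54), with medians of -0.14 without single-cultured replicate 2 and -0.36 without b.End5 replicate 2. Zonation genes fell in 15 of 30 and rose in 4 (median -1.33, adjusted p = 1.38e-06), the endothelin gene Edn1 by 7.61, or in 14 and 5 with a median of -0.76 without b.End5 replicate 2. Adjusted over the list alone, the counts of these 4 lists were the same, and these were the 4 of 17 called lists that passed with an estimated correlation. There were 8 without the array labelled b.End5 replicate 2, with amino acid transporters, mesenchymal genes, interferon genes and astrocyte markers (adjusted p = 0.0338, 0.0338, 0.0253 and 0.0417).

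Microglia and macrophage markers fell in 17 of 25 cases and rose in 1 between single-cultured cells and b.End5, also adjusted over the list alone (median -2.80, adjusted p = 1.44e-09, and adjusted p = 0.216 with an estimated correlation), Lyz2 by 8.46 (SE 0.27). Mesenchymal and matrix genes fell in 30 of 57 beside them and rose in 6 (6 and 31 adjusted over the list alone; median -1.30, adjusted p = 7.66e-14, and adjusted p = 0.0549 with an estimated correlation), Acta2 by 7.45 and Thbs1 by 7.32. Tip cell genes fell in 11 of 24 and rose in 2 (adjusted p = 5.11e-05, and adjusted p = 0.124 with an estimated correlation), Angpt2 by 6.82. Pericyte markers fell in 11 of 22 (adjusted p = 1.6e-04, and adjusted p = 0.246 with an estimated correlation), and both lists had the same counts adjusted over the list alone. Interferon genes rose in 14 of 31 and fell in 1 (14 and 2 adjusted over the list alone; median 0.93, adjusted p = 9.93e-05, and adjusted p = 0.498 with an estimated correlation), Ifit2 by 4.21, or rose in 21 with a median of 1.47, and adjusted p = 0.0253 with an estimated correlation, without b.End5 replicate 2. Klf2 (3.62, SE 0.39) and Klf4 (2.30, SE 0.25) were higher in b.End5 than in single-cultured cells, in a list of Wnt and barrier factors where 3 rose, or 5 without b.End5 replicate 2, and 10 fell of 32, also adjusted over the list alone (adjusted p = 0.00218, and adjusted p = 0.160 with an estimated correlation). Endothelial identity genes fell in 8 of 35 and rose in 2 (adjusted p = 0.0398, and adjusted p = 0.498 with an estimated correlation). Oligodendrocyte markers fell in 5 of 21 (adjusted p = 0.0131, and adjusted p = 0.167 with an estimated correlation), with the same counts adjusted over the list alone. The endothelial call ended with cyclic loess (adjusted p = 0.310), with centring on the housekeeping genes (adjusted p = 0.0623), or with the dimmest genes left out (adjusted p = 0.118). It also ended without single-cultured replicate 1 (adjusted p = 0.0938) or 3 (adjusted p = 0.0899) or b.End5 replicate 2 (adjusted p = 0.0571). Of all genes 2139 were called, 950 higher and 1189 lower, led by Igfbp5 (8.82), Serpina1b (at least 92.8-fold), Meis2 (at least 95.1-fold), the Notch ligand Dll1 (6.63) and Ifi202b (at least 62.3-fold). Beside Slco1a4 and Lyz2, the largest falls were the prion-like gene Prnd (-8.61), the lysophospholipase Enpp2 (-8.30) and the neuronal hydrolase Uchl1 (at least 162-fold). Without the array labelled b.End5 replicate 2 the count was 2294, 1059 higher and 1235 lower, and 1968 genes were called both ways. Arrays did not overlap in 41.5% of genes, where chance gives 10%.

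Across the 3 comparisons with non-cultured cells, 504 genes were called higher and 567 lower in all of them, Tfrc, Slc7a5, Slc3a2, Slc7a1, Slc38a3 and Slc38a5 among the lower. Independent lists of the same sizes would share 9.04 and 4.97 genes, and 100 simulations of unchanged groups against the same non-cultured arrays gave 0, a value that does not measure what shared arrays add among genes that did change. Without the array labelled b.End5 replicate 2 the numbers were 530 and 574, of which 481 and 546 were the same genes. The comparisons share their 3 non-cultured arrays, which are too few to split, so part of the overlap may come from them. Single-cultured and co-cultured cells had 948 genes higher and 761 lower in common and 1 called in opposite directions, while single-cultured cells and b.End5 had 541 and 615 in common and 104 in opposite directions.

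Whether co-culture moved genes back toward the non-cultured level was asked of the genes called both between the cultures and between single-cultured and non-cultured cells. Of these genes, 90 moved with glia in the direction that culture had moved them and 40 the opposite way, against 12.4 and 11.1 in independent lists and, with no effect in either comparison, 0 in simulated groups. The first group held 83 genes higher in both and the second 27 that culture had raised and glia lowered, and Bub1 and Ccnb1 of the cell cycle were in the first. Gja4 rose by 2.34 in culture and fell by 2.02 with glia, and Rgs5 fell by 5.79 and rose by 1.53. The covariance of the 2 shifts across all genes, where genes are not independent replicates, was 0.0120, against -0.0295 in simulated unchanged groups, in which the shared arrays give a negative value. The difference was 0.0416, and the covariance corrected for the shared noise was 0.0419 (jackknife SE 0.0318). Both take the arrays as independent, and with the covariance of same-numbered cultured arrays allowed for, an alternative chosen after seeing the data, the corrected value was 0.0372. Without allowing for it, the value was 0.0164 without co-cultured replicate 1 and 0.0665 without co-cultured replicate 3.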

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

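The test of a lower share of endothelial RNA given below was chosen only after the result was seen, and the second macrophage list and its bounds were fixed before its values were looked at.

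Microglia and macrophage markers lay in opposite directions in the primary cultures and in the line. Their median log2 difference from non-cultured cells was 1.55 in single-cultured cells and -1.19 in b.End5, and b.End5 differed from single-cultured cells by a median of -2.80 (adjusted p = 1.44e-09, and adjusted p = 0.216 with an estimated correlation). Without the array labelled b.End5 replicate 2 that median was -2.84 (adjusted p = 1.21e-08). Of the 25 measured genes, 24 lay above the no-target level on every non-cultured array, 22 on every single-cultured and every co-cultured array and 14 on every b.End5 array, and 0 belonged to another list. On each non-cultured array 81.0% to 82.2% of all genes lay above that level. Lying above it therefore does not show that cells sorted with PECAM1 beads expressed these markers.

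Macrophages or microglia that remained in cultures for which no bead sort is stated may account for the rise. A second list of 46 macrophage genes, with 0 in the fixed lists, had medians of 1.16 in single-cultured and 1.36 in co-cultured against non-cultured cells, where the bound was 1. This list would rise with carried-over macrophages and with induction in primary cells alike. In it 25 and 32 genes rose and 0 fell, or 26 and 33 adjusted over the list alone (adjusted p = 6.23e-12 and 2.10e-13, and adjusted p = 0.252 and 0.227 with an estimated correlation). Between the cultures it was called higher with glia (median 0.16, adjusted p = 0.0480, and adjusted p = 0.694 with an estimated correlation), but not without b.End5 replicate 2 (adjusted p = 0.0585). Of the 46, 33 lay above the no-target level on every non-cultured array, 42 on every single-cultured, 43 on every co-cultured and 27 on every b.End5 array. The member with the highest log2 value in single-cultured cells was the actin-bundling protein Lcp1. It lay at 10.39 in non-cultured, 12.25 in single-cultured and 11.82 in b.End5 cells, so that gene does not mark macrophages alone. The lectin Clec4d went from 5.12 to 9.76 and the perforin-like Mpeg1 from 6.51 to 9.72.

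Induction by culture in any brain endothelial cell could also raise such genes, but in b.End5 the second list had a median of -0.25, below the 0 set as the bound. A lower share of endothelial RNA would possibly raise markers of all other cells, yet 3 of 6 other marker lists were called lower in single-cultured cells, those of pericytes, astrocytes and blood cells. With an estimated correlation those 3 calls had adjusted p = 0.512, 0.153 and 0.0860, so none of them passed, and neither did the macrophage list, whose adjusted p over its alternatives lay between 2.14e-06 and that estimate of 0.374. The line has been in culture far longer than 5 days, so induction limited to primary cells was not tested and remains open, as does carry-over that differs between preparations.

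Transcripts with an accession but no gene symbol changed as well. Of 5024 such probe sets 192 were higher in single-cultured, 251 in co-cultured and 358 in b.End5 than in non-cultured cells, and 241, 279 and 317 were lower. The share called was 8.62%, 10.5% and 13.4%, below the share among named genes in each case. They could not be grouped by function here.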

How the results depend on the processing

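None of the alternatives reversed the sign of a called gene among the 495 named values, or the direction of a called list test. The medians of 3 called lists in b.End5 against single-cultured cells, all near 0, did change sign when 1 array was left out. That of amino acid transporters went from -0.01 to 0.0208 without b.End5 replicate 1 and 0.0169 without single-cultured replicate 2, that of endothelial identity from -0.07 to 0.03 without single-cultured replicate 3, where its call ended, and that of oligodendrocyte markers from -0.03 to 0.07 without single-cultured replicate 3 and 0.00793 without b.End5 replicate 2. Without a minimum difference the genes called rose from 1976 to 4294 in single-cultured, 2326 to 5224 in co-cultured and 2761 to 5774 in b.End5 against non-cultured cells, and to 383 and 4591 in co-cultured and b.End5 against single-cultured cells. With limma treat, which tests against the 2-fold minimum itself, the same 5 counts were 802, 990, 1434, 2 and 883. Between the cultures, 97 genes were called at an adjusted p under 0.01 and 288 with array weights, where the array labelled b.End5 replicate 2 had the lowest weight (0.230). That count of 181 was 118 without single-cultured replicate 1 and 231 without b.End5 replicate 2.

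Among amino acid transporters, 26 were called in co-cultured against non-cultured cells without a minimum, against 17 with it, and 9 with treat. Between the cultures the count of 2 became 4 without a minimum, 1 at an adjusted p under 0.01 or with the dimmest 30% of genes left out, and 0 with treat or a model of only the 2 groups. It was 1 without single-cultured replicate 1 or 3 or co-cultured replicate 2 or 3, and 3 without b.End5 replicate 2. In b.End5 against single-cultured cells 5 were called with treat.

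Of the gene lists called, 4 of 14, 5 of 16, 7 of 16, 2 of 10 and 4 of 17 remained with an estimated correlation, in the same order of comparisons, and 6, 6, 8, 2 and 8 without b.End5 replicate 2. With the replicate block over all arrays 1970, 2315, 2753, 174 and 2130 genes were called, no list call changed and 5 named values lost their call. Of the pairs with the same number 5 of 18 correlated above 0.1, and 0 of 12 arrays correlated best with their own number in every other group. The replicate block among the cultured arrays gave 202 genes, 3 amino acid transporters and 12 lists between the cultures, and called ABC transporters lower (adjusted p = 0.0477, and adjusted p = 0.167 with an estimated correlation) beside the changes given in the report. Of the named values between the cultures, that block added a call to 2, Slc1a5 among them, and ended the call of 1. Leaving out single arrays gave 1860 to 2066, 2210 to 2397, 2653 to 2842 and 2046 to 2294 genes in the comparisons not given above, and 1016 to 1104 genes called the same way in all 3 cultured sources against 1071 with every array. The mean of the probe sets changed the call of 3 named values and the most variable probe set that of 0. The minimum difference, treat and the lower adjusted p change the counts by construction, and for array weights, the left-out arrays and the model of 2 groups the cause was not tested. Signal over background limits the genes near the no-target level. Bounds are given only where every array of a group lay at or under it. Plain differences such as those of Prnd, Enpp2 and Slco1c1 in b.End5, with some arrays under it, are limited too.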

Other observations

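The tests on the array labelled b.End5 replicate 2 were chosen only after the result was seen, as were the individual genes named in this part, while the other splits of the arrays, the heat-shock list and the scaling test were fixed beforehand.

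Transferrin receptor transcripts could be followed on separate control probe sets as well. The control for the 3' region went from 11.1 in non-cultured to 8.28 in single-cultured, 8.06 in co-cultured and 6.39 in b.End5 cells, the same order as the gene itself. Among heat-shock genes, the chaperone partner Dnajb1 fell by 2.40 in single-cultured, 2.29 in co-cultured and 2.63 in b.End5 cells, the small heat-shock protein Hspb1 by 1.68, 1.56 and 6.80 and the chaperone Hsp90aa1 by 1.24, 1.03 and 1.54. The lens and muscle chaperone Cryab rose by 3.04 and 3.25 in the 2 cultures and Hspa4l by 1.85 in both, while in b.End5 neither passed (0.86 and 0.91).

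Immediate early genes were high in non-cultured cells and lower in all 3 cultured sources. Stress during isolation, which induces such genes within minutes, may have raised them in the non-cultured cells. The bound set beforehand was a median of -0.5 or lower for a second heat-shock list in all 3 comparisons, and the medians were -0.22, -0.20 and 0.0312, all above the -0.25 that had been set to count against this reading. That bound was judged unfit only after the values were seen, since members of the list went both ways, so the 2 readings cannot be told apart by it (2, 3 and 0 of 18 rose and 3, 3 and 4 fell, also adjusted over the list alone; adjusted p = 0.385, 0.827 and 0.203). In b.End5 the mean was -0.62 against that median of 0.0312, which was -0.07 without the array labelled b.End5 replicate 2. The heat-shock gene Hspa1b was counted in the immediate early list instead. It had a mean of 13.64 in non-cultured, 6.80 in single-cultured, 6.83 in co-cultured and 7.24 in b.End5 cells. The scaling between arrays is not a likely source, since the highest median of the immediate early list over 3 scalings and 3 comparisons was -2.60. A loss of signals that act in the vessel, such as flow, was not tested.

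The array labelled b.End5 replicate 2 differed from replicates 1 and 3 in 420 genes that were over 1 log2 unit higher and 653 that were lower. It had Xist, transcribed from the inactive X chromosome, at 6.20 against 11.09 to 12.48 on the other arrays, and the Y-linked genes Ddx3y at 7.84, Eif2s3y at 9.24, Kdm5d at 5.38 and Uty at 5.93, while the highest value of these 4 on the other 11 arrays was 3.42. A swap need not leave such transcripts on another array, so these genes alone cannot decide on one. The array correlated at 0.968 and 0.969 with the other b.End5 arrays and at most at 0.918 with those of other groups. A swap within the series is therefore not a likely source. Poor RNA may be considered, but the difference between 3' and 5' Gapdh controls was 2.81, inside the 1.94 to 3.97 of the other arrays. The 3.97 belonged to single-cultured replicate 2, and the next highest value was 3.48 on non-cultured replicate 2. A mixture with a substantial share of b.End5 RNA could hardly lower a gene by over 2, yet 41 of 2518 genes at 10 or more in replicates 1 and 3 lay over 2 lower, against 0 between those 2 arrays. That bound was changed after a first one, 10 genes over 4 lower, gave 9. Endothelial genes were high on it, Pecam1 at 11.94, Cdh5 at 12.04 and Cldn5 at 13.35, so RNA of another endothelial line under this label remains open and untested.

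For each of the 5 comparisons the 6 arrays were also split in every other way into 3 and 3. The real split was the 1 of 10 with the most genes called, and the highest other split called 0. With 10 splits no share can fall below 0.1, so a share under 0.05 cannot be reached.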
